A study of Mus musculus with 6 samples.

How the data were processed

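The samples are RNA from pooled polysome fractions of mouse T-ALL clone #483, 3 control and 3 treated with 100 µM 4EGI-1 for 2 h, and the design text calls them biological replicates. Per the labels' protocols, RNA was amplified with a whole-transcript system and hybridised as fragmented, biotin-labelled cDNA. The deposited values are log2 signals, 1 per probe set and array, made with RMA per the submitters' processing notes. The software version, background setting and summary level are not given in the sources used here. RMA equalises the arrays, so values are relative within an array. Detection calls were not used here, so genes near the lower end of the signal were tested like the others. Groups were taken from the sample titles.

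The table holds 34760 probe sets, of which the platform annotation lists 22961. Of these, 21640 have 1 gene symbol and 1321 several, and 11799 probe sets are not listed and stay unnamed here. Symbols were updated by Entrez identifier, which matched 21553 probe sets, through a RefSeq gene table of assembly GRCm38.p6. That table was used only for names and for which genes neighbour each other. Probe sets with several symbols named no gene. For each symbol the probe set with the highest mean over the 6 arrays was kept, giving 19937 genes, of which 954 had several probe sets.

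Differences (4EGI-1 minus control) were fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, on the deposited log2 values with no filter and no further normalization. All tests are two-sided unless stated otherwise. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. SE is the moderated standard error. The residual degrees of freedom were 8.15 including a prior of 4.15. The median SD over genes was 0.0837 in controls and 0.0895 with 4EGI-1, and the median SE of a difference was 0.0781. The number of arrays limits the precision. No 2 arrays of a group were alike enough to be one sample deposited more than once; the smallest median absolute difference of a pair was 0.0927.

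There were 30 gene lists written before the data were examined, and 29 were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists. The list of mitochondrially encoded transcripts matched 0 annotated symbols and was not tested. Lists with at least 5 measured genes were tested. The lists were ribosomal proteins, other TOP mRNAs, snoRNA host RNAs, nuclear or untranslated RNAs, mitochondrial ribosomal proteins, oxidative phosphorylation, eIF4E-sensitive mRNAs, Notch and T-ALL oncogenes, the PI3K-AKT-mTOR pathway and translation initiation factors. Further lists were the ATF4 response, the unfolded protein response, NRF2 targets, heat shock proteins, cholesterol synthesis, glycolysis, the proteasome, DNA replication, mitosis, histones (matched by symbol pattern), p53 targets, the BCL2 family, immediate early genes and NF-kB targets. T-cell genes and markers of B cells, myeloid, erythroid and of stromal and endothelial cells completed them. Some genes belong to several lists.

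The genes named were set by a rule fixed before the data were examined. It took the 10 largest increases and the 10 largest decreases among genes that passed, whose groups did not overlap and whose higher group lay above the median of all genes. Predicted and unnamed genes were skipped (0 among increases, 1 among decreases). It also took the 3 members with the smallest adjusted p of each list that passed camera, up to 2 members that passed in each other list, and 18 fixed genes. Eif4g1, one of these 18, had no probe set with its symbol alone. In all, 92 genes were named in this way, and genes outside the rule were chosen after their values were seen.

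The scripts were tested on simulated data with the spread of these arrays, 19937 genes in all. Of genes changed by 0.5 on the log2 scale 58.2% were recovered, of those changed by 1 90.9%, and of those changed by 0.25 1.5%. Of the calls, 4.8% were false. Only 67, 66 and 67 genes were changed by these sizes, far fewer than were called in the data. The adjusted threshold was therefore stricter in the simulation, and these shares are not the recovery to be had in the data. A list shifted by 0.3 was called and 0 of 28 unshifted lists were. Genes were simulated independently and the lists were random, so this does not show how often lists of correlated genes are called falsely.

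Alternatives were the replicate number as a block, a filter at the median or the 25th percentile of the table, every probe set tested, the mean of a gene's probe sets, quantile normalization, centring outside ribosomal proteins, a trended robust prior, array weights, an adjusted p under 0.01 and leaving out each sample. For lists they were an estimated correlation, a rank-based camera and fry. Chosen after seeing the data were list medians relative to 200 genes of like signal, the ATF4 list without tRNA synthetases or without mRNAs with upstream reading frames, and 2-fold changes kept to genes at or above the median of the table. Medians of lists were compared by permutation tests with 100000 draws, two-sided, with 95% intervals from 10000 bootstrap draws over genes; genes are not independent replicates.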

Results

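RNA bound to polysomes was profiled in a mouse T-cell acute lymphoblastic leukaemia (T-ALL) clone, #483, of C57BL6 background. Cells were treated for 2 h with 100 µM 4EGI-1, a small molecule that blocks the binding of the cap-binding protein eIF4E to the scaffold eIF4G, or were left as controls. Lysates were separated on sucrose gradients and the RNA of the pooled polysome fractions was hybridised to 1 array per sample, with 3 control and 3 treated samples. The control samples are titled untreated, while the treatment protocol names the solvent DMSO, so whether the controls received solvent is not settled. The comparison asks which mRNAs were more or less abundant on polysomes after treatment with 4EGI-1. The arrays do not measure the binding of eIF4E to eIF4G, so other effects of the compound are not separated from its inhibition. Median log2 signal per array was 6.38 to 6.43 over 34760 probe sets, and the number of arrays limits the precision. Arrays of one group correlated at 0.996 to 0.997 and arrays of different groups at 0.988 to 0.990 across the genes tested, with 1 probe set per gene.

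After 4EGI-1, polysomal mRNAs of mitochondrial proteins, cytosolic ribosomal proteins and cholesterol synthesis enzymes were lower as lists, and the list of the ATF4 stress response was higher, with 17 of its 37 measured genes up. These lists passed camera with a preset correlation between genes and not with their own: adjusted p = 0.650 with an estimated correlation for cholesterol synthesis, and adjusted p = 0.193 with an estimated correlation for the other 4. A list of short-protein genes, some of them mitochondrial, was written after the fall of mitochondrial genes was seen. Its median log2 difference was -0.40, with 60 of 80 genes lower, so the fall was not confined to the lists named above. Ccnd1, which encodes the G1 cyclin D1, was among the 10 largest decreases chosen by the rule. It fell from a log2 signal of 10.66 ± 0.10 to 9.41 ± 0.08 (SD, n = 3 each). Slc7a11, which encodes the cystine transporter subunit and is an ATF4 target, rose from 10.74 ± 0.04 to 11.95 ± 0.07 (SD, n = 3 each). Myc, the oncogenic transcription factor, and the survival genes Mcl1 and Bcl2 did not pass the test.

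Of 19937 genes tested with limma, 4573 changed at an adjusted p under 0.05, which is 22.9%. Of these, 2286 were higher and 2287 lower with 4EGI-1. Most changes were small: the median absolute log2 difference of the changed genes was 0.40, and 77.0% of them changed by less than 1.5-fold. At 2-fold or more, 153 genes were higher and 27 lower. The values of the groups did not overlap in 37.9% of genes, against 10% by chance. The median log2 difference over all genes was -0.03.

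**Figure D1:**
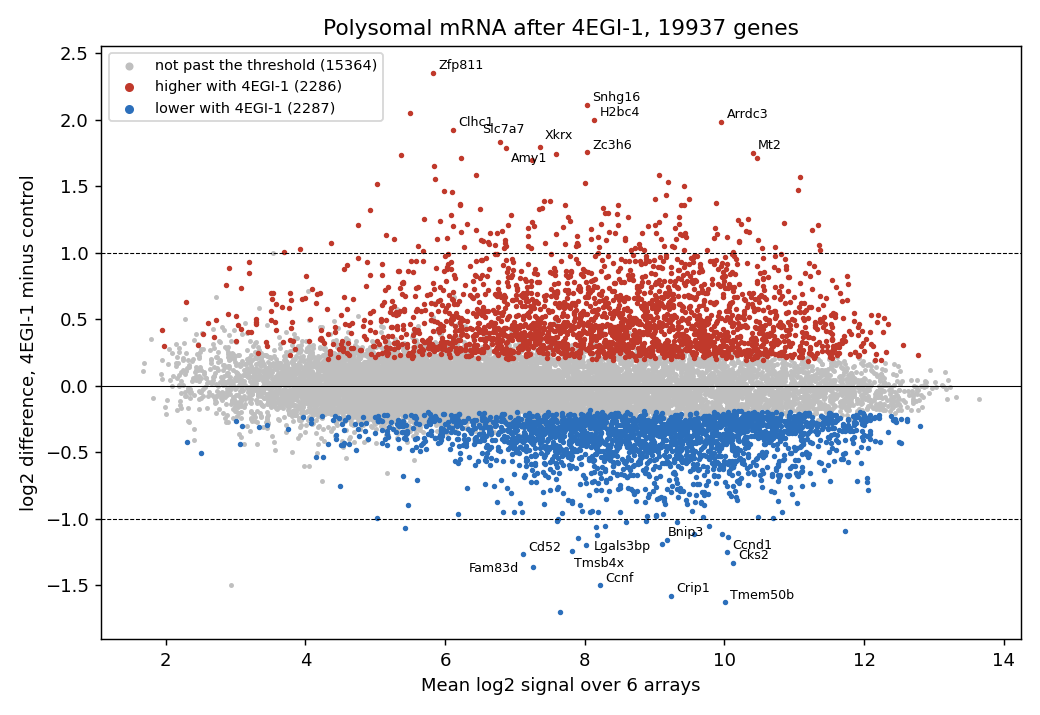
Log2 difference (4EGI-1 minus control) of each of 19937 genes against its mean log2 signal over 6 arrays, with 2286 genes higher (red), 2287 lower (blue) and the rest in grey. Dashed lines mark 2-fold, which 153 genes passed upward and 27 downward; the labelled genes are the 10 of each direction chosen by the rule for named genes.

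The 10 largest increases chosen by the rule were in genes of varied function. Zfp811, a zinc finger gene (probe set 10449920), rose by 2.35 ± 0.09 on the log2 scale (SE; adjusted p = 2.8e-05), from a low control signal of 4.66. Arrdc3, an arrestin-domain gene, rose by 1.99 ± 0.09 and the metallothionein gene Mt2 by 1.75 ± 0.11. The snoRNA host gene Snhg16 rose by 2.11 ± 0.19 and the histone gene H2bc4 by 2.00 ± 0.09; histone genes have near-identical copies, so the value of H2bc4 is uncertain. Clhc1 (1.92), Slc7a7 (1.84), Xkrx (1.80), the amylase gene Amy1 (1.79) and Zc3h6 (1.75) completed the 10. Slc7a7, an amino acid transporter gene, lies within 1 kb of Oxa1l, which also rose, and the array values do not separate overlapping transcripts.

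The 10 largest decreases chosen by the rule were also in genes of varied function. Ccnf, which encodes cyclin F, fell to 0.353 times its control level, and Cks2, a cyclin-dependent kinase subunit, fell by 1.34 ± 0.08 on the log2 scale (SE). Fam83d, a spindle protein gene, fell by 1.36 ± 0.08 and Ccnd1 by 1.25 ± 0.08. Tmem50b fell most among the named genes, by 1.63 ± 0.10, followed by Crip1, which fell by 1.58 ± 0.12. The remaining 4 were the lymphocyte surface antigen gene Cd52 (-1.27), the thymosin gene Tmsb4x (-1.24), Lgals3bp (-1.20) and the mitophagy receptor gene Bnip3 (-1.19).

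Of the 29 gene lists tested with camera, 8 shifted at an adjusted p under 0.05 with a preset correlation of 0.01 between genes, and 0 did with an estimated correlation, where camera gave 4 lists an unadjusted p under 0.05. The rotation test fry, which asks only whether a list's own genes move one way, called 13. The 8 lists are given first.

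Nuclear genes of oxidative phosphorylation encode subunits of the respiratory chain and ATP synthase. They were lower, with the smallest camera p of the 29 lists tested with the preset correlation. Of 72 measured, 52 fell, 1 rose and 19 did not pass (56 fell and 2 rose adjusted over the list alone), with a median log2 difference of -0.31 (camera adjusted p = 9.76e-16). This list did not pass with its own correlation (adjusted p = 0.193 with an estimated correlation). Uqcrh of complex III fell by 0.79 ± 0.06 (SE), Sdhd of complex II by 0.83 ± 0.07 and Ndufa5 of complex I by 0.81 ± 0.07. Mitochondrial ribosomal protein genes moved the same way: of 74 measured, 41 fell, 1 rose and 32 did not pass (51 fell and 2 rose adjusted over the list alone; median -0.27, camera adjusted p = 1.86e-12). Here too the call was lost (adjusted p = 0.193 with an estimated correlation). Mrpl42 fell by 1.11 ± 0.08, Mrps12 by 0.84 ± 0.06 and Mrpl51 by 0.82 ± 0.06.

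Cytosolic ribosomal protein genes, whose mRNAs begin with a terminal oligopyrimidine (TOP) motif, fell by less. Of 55 measured, 19 fell, 0 rose and 36 did not pass (25 fell adjusted over the list alone), with a median of -0.16 (camera adjusted p = 2.84e-06; adjusted p = 0.193 with an estimated correlation). Rps28 fell by 0.68 ± 0.08 (SE), Fau by 0.50 ± 0.06 and Rps14 by 0.43 ± 0.07. The list holds 79 genes; many of the others share a probe set with other genes. Among other TOP mRNAs, 1 of 23 measured rose, 1 fell and 21 did not pass, also adjusted over the list alone, with a median of -0.07 (camera adjusted p = 0.303). The elongation factor gene Eef2 rose by 0.53 ± 0.06 and Imp3, a factor for ribosome assembly, fell by 0.64 ± 0.07.

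Genes of the ATF4 and integrated stress response, the programme that follows phosphorylation of eIF2α or amino acid shortage, were higher as a list, though most members did not pass. Of 37 measured, 17 rose, 0 fell and 20 did not pass (20 rose and 1 fell adjusted over the list alone), with a median of 0.20 (camera adjusted p = 6.55e-09; adjusted p = 0.193 with an estimated correlation). Slc7a11 rose by 1.21 ± 0.06 (SE), the glutamyl-prolyl-tRNA synthetase gene Eprs by 1.17 ± 0.06 and Slc3a2, a heavy chain of amino acid transporters, by 1.02 ± 0.06. Other known targets did not pass, with log2 differences of 0.07 for Asns, 0.00 for Psat1, 0.04 for Slc7a5, -0.08 for Mthfd2, -0.15 for Phgdh and -0.23 for Atf5. Atf4 itself rose by 0.48 ± 0.06 and its target Ddit3, which encodes CHOP, by 0.86 ± 0.07. Genes of endoplasmic reticulum chaperones and the unfolded protein response did not shift as a list: 3 of 25 rose, 3 fell and 19 did not pass (3 and 4 adjusted over the list alone), with a median of -0.03 and a mean of 0.01 (camera adjusted p = 0.923, direction down). Herpud1 rose by 1.12 ± 0.06 and the translocon gene Sec61b fell by 0.81 ± 0.08, while the difference for the chaperone gene Hspa5 was 0.05 ± 0.06 (adjusted p = 0.611).

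Genes of cholesterol synthesis and SREBP2 targets were lower. Of 20 measured, 13 fell, 0 rose and 7 did not pass (15 fell adjusted over the list alone), with a median of -0.31 (camera adjusted p = 1.75e-06; adjusted p = 0.650 with an estimated correlation). Sqle, which encodes squalene epoxidase, fell by 0.65 ± 0.06 (SE), the sterol sensor gene Insig1 by 0.51 ± 0.07 and Srebf2, which encodes the transcription factor SREBP2, by 0.48 ± 0.06.

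The list of mRNAs known from reviews as sensitive to eIF4E was lower on balance, by a margin that depended on the setting. Of 26 measured, 10 fell, 3 rose and 13 did not pass (10 fell and 4 rose adjusted over the list alone), with a median of -0.12 (camera adjusted p = 0.0482; adjusted p = 0.766 with an estimated correlation). The camera adjusted p was 0.132 without control replicate 1, 0.0648 without control replicate 3, 0.0685 without 4EGI-1 replicate 2 and 0.0645 without 4EGI-1 replicate 3. Quantile normalization gave 0.0797, the rank-based test 0.0829 and the replicate block 0.0539. Leaving out genes under the median or the 25th percentile of all probe sets gave 0.135 and 0.0717. Ccnd1 fell by 1.25 ± 0.08 (SE), Fth1, the ferritin heavy chain gene, by 0.76 ± 0.06 and the survivin gene Birc5 by 0.61 ± 0.06. The cyclin D genes Ccnd2 and Ccnd3 fell by 0.69 ± 0.09 and 0.43 ± 0.08. The ornithine decarboxylase gene Odc1 fell by 0.29 ± 0.07; its adjusted p was 0.0537 without control replicate 1 and 0.0531 without 4EGI-1 replicate 1. The log2 differences of Myc, Mcl1 and Bcl2 were 0.18 ± 0.06 (adjusted p = 0.0801), -0.18 ± 0.09 (0.222) and 0.00 ± 0.07 (0.986). Myc passed in 3 alternatives, with an adjusted p of 0.0251 among genes at or above the median of the table, 0.0205 after quantile normalization and 0.00320 with a trended robust prior.

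DNA replication genes moved in both directions, with a small net increase. Of 40 measured, 14 rose, 10 fell and 16 did not pass (14 rose and 11 fell adjusted over the list alone; median 0.10, camera adjusted p = 0.0193, adjusted p = 0.766 with an estimated correlation). The call ended without control replicate 2 (adjusted p = 0.0534), among genes at or above the median of the table (0.0550) and in the rank-based test (0.114). The DNA polymerase genes Pole and Pola1 rose by 1.40 ± 0.07 and 1.04 ± 0.06 (SE), and the ribonucleotide reductase gene Rrm1 by 0.80 ± 0.07. Among mitosis genes 18 of 35 fell, 9 rose and 8 did not pass, also adjusted over the list alone, with a median of -0.23 (camera adjusted p = 0.123; 0.0492 without 4EGI-1 replicate 1 and 0.0232 in fry). Cks2 fell by 1.34 ± 0.08 and the mitotic kinase gene Aurka by 0.89 ± 0.07. The histone list, meant for replication-dependent genes but matched by symbol pattern, also held other variants (H2az1, H2az2, H2ab1, H2al3 and H2bl1). It showed 5 of 33 higher, 4 lower and 24 not past the test, also adjusted over the list alone (median -0.02, mean 0.07, camera adjusted p = 0.881, direction up). H2bc4, which has near-identical gene copies, rose by 2.00 ± 0.09 and H1f2 by 1.21 ± 0.11.

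Of the non-coding snoRNA host RNAs, 5 of 15 were measured, of which 3 rose, 0 fell and 2 did not pass, also adjusted over the list alone (median 0.26, camera adjusted p = 0.0193, adjusted p = 0.644 with an estimated correlation). Snhg5 rose by 1.22 ± 0.07 (SE) and Snhg17 by 0.59 ± 0.12. Gas5 was 0.26 ± 0.06 higher by its brightest probe set, but the other 3 of its 4 probe sets went down, to as low as -1.26. With the mean of each gene's probe sets Gas5 was at -0.72 (adjusted p = 0.000176), Snhg17 at 0.22 (adjusted p = 0.0546), and the list did not pass (adjusted p = 0.546); it also did not pass the rank-based test (0.0829). The adjusted p of Gas5 was 0.0534 without control replicate 3 and 0.0521 without 4EGI-1 replicate 3. Of 7 nuclear or untranslated RNAs, 0 rose, 1 fell and 6 did not pass (2 fell adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.821). The member that fell was Malat1, an abundant nuclear RNA, by 0.28 ± 0.07 (adjusted p = 0.0218; 0.0762 without control replicate 2, 0.0702 without control replicate 3, 0.0695 without 4EGI-1 replicate 1 and 0.05002 with every probe set tested).

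**Figure D2:**
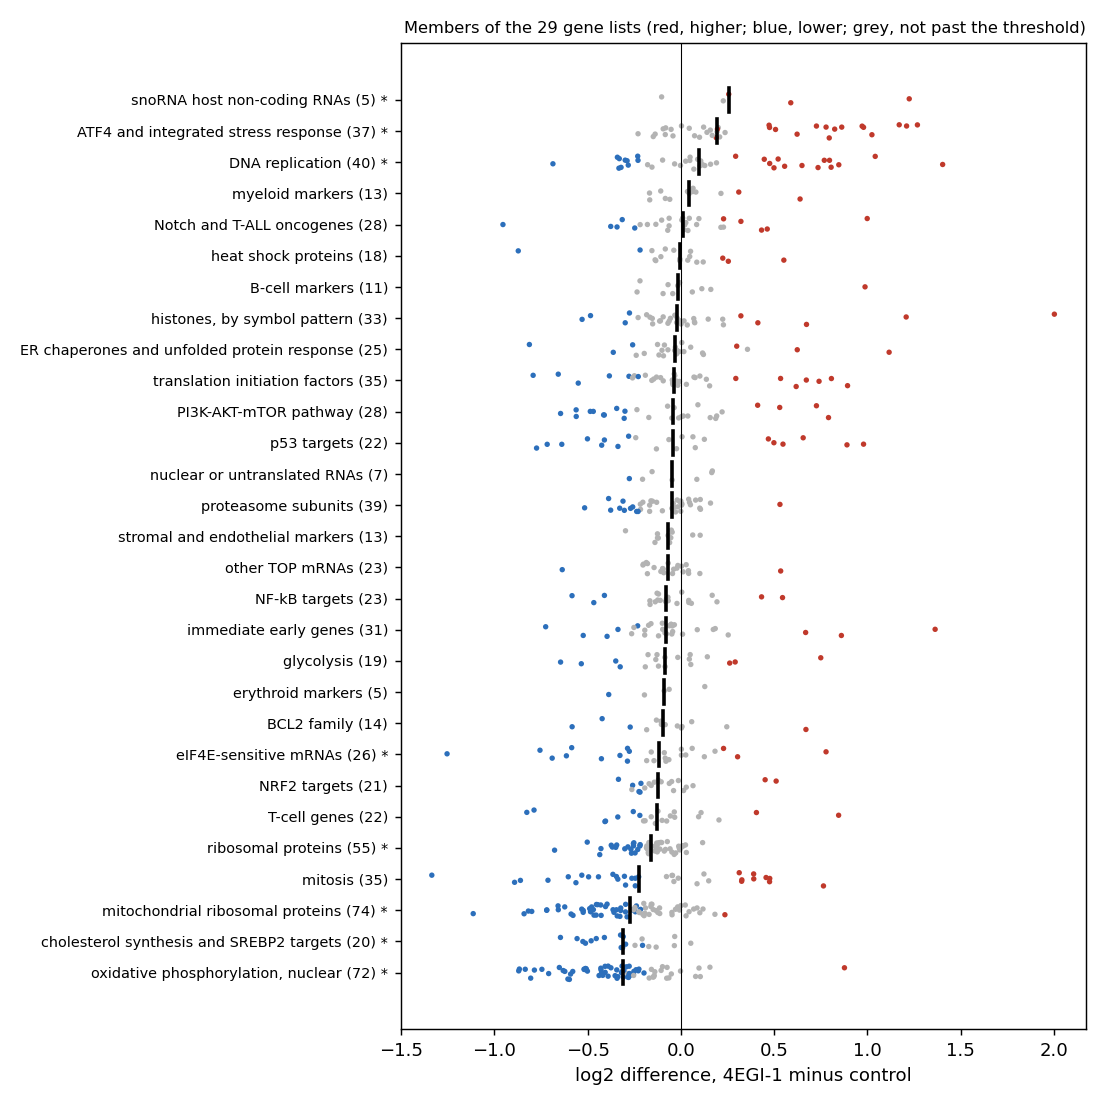
Log2 difference (4EGI-1 minus control) of the measured members of 29 gene lists, with the number measured in brackets; each point is a gene, red where higher, blue where lower and grey where it did not pass, and the black bar is the list median. Asterisks mark the 8 lists that passed camera with the preset correlation; medians run from -0.31 for oxidative phosphorylation to 0.26 for snoRNA host RNAs.

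Components of the targeted pathway changed individually. Eif4e fell by 0.28 ± 0.06 on the log2 scale (SE; adjusted p = 0.0148). The eIF4E-binding repressor genes went opposite ways: Eif4ebp1 rose by 0.41 ± 0.07 and Eif4ebp2 fell by 0.47 ± 0.06. Eif4g1 had no probe set of its own name alone and is not reported. Among translation initiation factors 7 of 35 rose, 6 fell and 22 did not pass (7 and 8 adjusted over the list alone; median -0.04, mean 0.02, camera adjusted p = 0.881, direction up). Eif5b, the factor for ribosomal subunit joining, rose by 0.89 ± 0.06 and Eif2ak3, which encodes the eIF2α kinase PERK, by 0.81 ± 0.06. In the PI3K-AKT-mTOR pathway 4 of 28 rose, 10 fell and 14 did not pass (8 and 11 adjusted over the list alone; median -0.04, camera adjusted p = 0.523; 0.0342 in fry). Mtor rose by 0.79 ± 0.08 and Pdk1, a pyruvate dehydrogenase kinase gene that is also in the glycolysis list, fell by 0.64 ± 0.07. Pdk1 is not the gene of the pathway kinase PDK1, though it counts among the 10 that fell. That kinase is encoded by Pdpk1, also in the list, which differed by 0.01 ± 0.06 (adjusted p = 0.922).

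Notch and T-ALL oncogenes did not shift as a list: 5 of 28 rose, 5 fell and 18 did not pass, also adjusted over the list alone (median 0.01, camera adjusted p = 0.872). Hes1, a direct Notch target, rose by 1.00 ± 0.08 (SE) and Notch1 by 0.32 ± 0.06, while the Notch target Nrarp fell by 0.95 ± 0.10 and the pre-T-cell receptor gene Ptcra by 0.34 ± 0.06. The interleukin 7 receptor gene Il7r differed by 0.21 ± 0.11 (adjusted p = 0.221). Of 22 T-cell genes 7 fell, 2 rose and 13 did not pass (9 and 3 adjusted over the list alone; median -0.13, camera adjusted p = 0.0822). The list passed without 4EGI-1 replicate 1 (adjusted p = 0.0244), with every probe set tested (0.0439), with a trended robust prior (0.0380) and in fry (0.0133). The surface receptor genes Cd27 and Cd2 fell by 0.83 ± 0.07 and 0.79 ± 0.07.

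**Figure D3:**
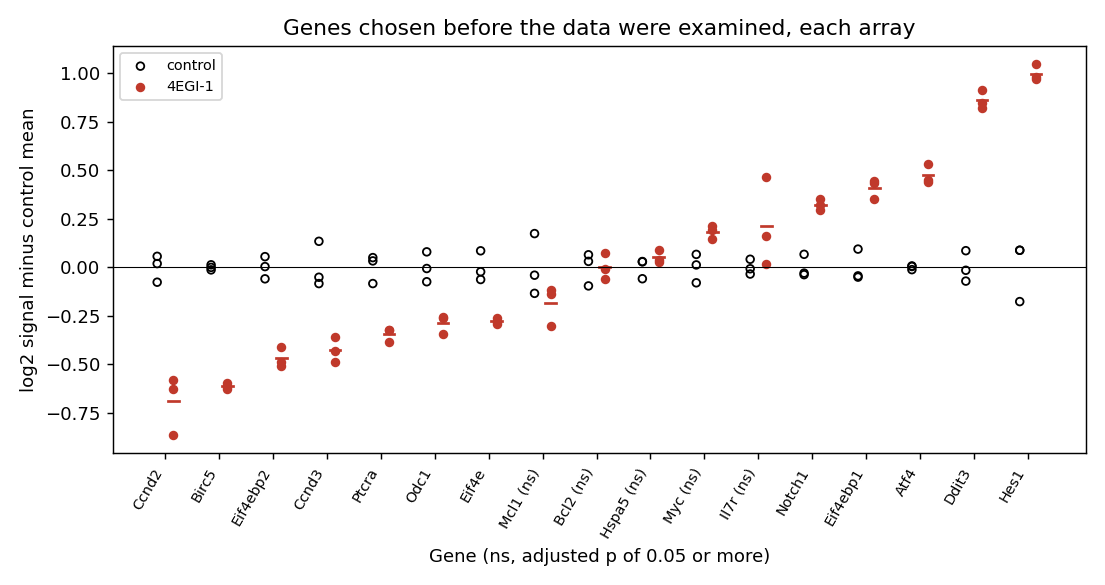
Log2 signal minus the control mean for each of 3 control (open circles) and 3 4EGI-1 (filled circles, bar at the mean) arrays, for the 17 measured genes of the set of 18. With 4EGI-1, 5 were higher, 7 lower and 5 did not pass (ns), from Ccnd2 at -0.69 to Hes1 at 1.00.

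The lists of death, stress and signalling genes did not pass camera, while fry called the BCL2 family (adjusted p = 0.0293) and NRF2 targets (adjusted p = 0.0246). In the BCL2 family 1 of 14 rose, 3 fell and 10 did not pass (2 and 3 adjusted over the list alone; median -0.09, adjusted p = 0.523), with the pro-apoptotic Bcl2l11 up by 0.67 ± 0.09 (SE) and Bid down at -0.58 ± 0.07. Among p53 targets 6 of 22 rose, 8 fell and 8 did not pass (6 and 9 adjusted over the list alone; median -0.04, adjusted p = 0.872), with Sesn2, also an ATF4 target, up by 0.98 ± 0.07 and Trp53inp1 down at -0.77 ± 0.06. Of 31 immediate early genes 3 rose, 5 fell and 23 did not pass (3 and 6 adjusted over the list alone; median -0.08, adjusted p = 0.523); Jun rose by 1.36 ± 0.13 and Ier5 fell by 0.72 ± 0.07. NF-kB targets gave 2 of 23 higher, 3 lower and 18 not past the test, also adjusted over the list alone (median -0.08, adjusted p = 0.723), with Il2ra up by 0.54 ± 0.07 and Nfkb2 by 0.43 ± 0.07. Of 18 heat shock protein genes 3 rose, 2 fell and 13 did not pass, also adjusted over the list alone (median -0.01, adjusted p = 0.923, direction up); the co-chaperone gene Dnajb1 fell by 0.87 ± 0.07 and Hsph1 rose by 0.55 ± 0.07. NRF2 targets gave 2 of 21 higher, 5 lower and 14 not past the test, also adjusted over the list alone (median -0.12, adjusted p = 0.271), with Tkt up by 0.51 ± 0.07 and Gsr, glutathione reductase, down at -0.33 ± 0.06.

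Of 39 proteasome subunit genes 10 fell, 1 rose and 28 did not pass (13 and 1 adjusted over the list alone), with a median of -0.05 (camera adjusted p = 0.0615). The list passed without control replicate 2 (adjusted p = 0.0137), without control replicate 3 (0.0363) and without 4EGI-1 replicate 1 (0.0358). It also passed with every probe set tested (0.0270), with the mean of a gene's probe sets (0.0429) and with a trended robust prior (0.0143). Psma5 fell by 0.52 ± 0.09 (SE) and Psmd1 rose by 0.53 ± 0.06. Among glycolysis genes 3 of 19 rose, 4 fell and 12 did not pass (3 and 5 adjusted over the list alone; median -0.09, adjusted p = 0.523), with the hexokinase gene Hk2 up by 0.75 ± 0.08.

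Markers of other cell types did not shift as lists. Of 13 myeloid markers 2 rose, 0 fell and 11 did not pass (median 0.04, adjusted p = 0.523): Adgre1 by 0.64 ± 0.08 (SE), at a control signal of 4.92, and Cd68 by 0.31 ± 0.07. Of 11 B-cell markers 1 rose and 10 did not pass (median -0.02, mean 0.06, adjusted p = 0.829, direction up), namely Blnk by 0.99 ± 0.11. Of 5 erythroid markers 1 fell and 4 did not pass (median -0.09, adjusted p = 0.523), namely Car1 by 0.39 ± 0.09. Of 13 stromal and endothelial markers 0 changed (median -0.07, adjusted p = 0.523). These counts were the same adjusted over the list alone. The adjusted p of Cd68 was 0.0634 without control replicate 1 and 0.0606 without 4EGI-1 replicate 3, and that of Car1 was 0.0543 without 4EGI-1 replicate 2.

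The values are relative within each array, so a general loss of mRNA from polysomes does not show. No arrays of unfractionated RNA were used here, so a change on polysomes holds both transcript level and ribosome loading.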

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

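The tests of the TOP motif, of nuclear RNA, of medians relative to genes of like signal, of the shortened ATF4 lists and of short proteins from long transcripts (a list that holds Rab genes, written after the fall of the Rab family was seen) were chosen after the result was seen. The lists of short and long proteins were written after the fall of mitochondrial genes was seen but before the values of their own members were.

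Probe sets outside the named genes also moved. Of the 11799 unnamed probe sets, 195 were at least 2-fold higher with 4EGI-1 and 47 at least 2-fold lower. Of the 1321 probe sets of several genes, 16 were at least 2-fold higher and 7 lower.

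Genes of long proteins rose and genes of short proteins fell, which is a hypothesis about coding length found in these data. Of 125 long-protein genes 86 rose and 3 fell, and of 80 short-protein genes 60 fell and 0 rose; the medians differed by 0.845 on the log2 scale (95% interval 0.730 to 0.913; permutation p = 1e-05, the smallest these draws can give), and by 0.810 relative to genes of like signal, which argues against signal level. The camera p with the preset correlation was 9.8e-29 for the long and 1.1e-20 for the short list. With an estimated correlation the camera p was 0.0600 for the long and 0.0741 for the short list, so neither list alone passed that test. Short proteins from long transcripts had a median of -0.24 (95% interval -0.37 to -0.12). That list holds Rab genes and was written after their fall was seen, so it cannot test transcript length or RNA integrity independently. Other TOP mRNAs lay 0.0900 above ribosomal proteins (permutation p = 0.0140). This comparison was chosen after the result was seen, so it cannot test the TOP motif independently. Oxidative phosphorylation genes did not lie below the short proteins (difference 0.0927, interval 0.00593 to 0.154, permutation p = 0.0620), against a fall particular to them. The short list itself holds mitochondrial genes such as Timm8b and Tomm7, which weakens that comparison. Ribosomal proteins lay 0.247 above the short proteins (interval 0.174 to 0.3085, permutation p = 1e-05) and mitochondrial ribosomal proteins 0.131 (0.0237 to 0.211, permutation p = 0.0124). Both thus fell by less than the short list. Fewer ribosomes per mRNA could move short mRNAs out of the pooled fractions first, which stays open, as do the choice of fractions and transcript level, and exact coding lengths were not used here.

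The rise of ATF4 genes may be a stress response to the treatment, as a hypothesis. Without the tRNA synthetases the list still passed with the preset correlation (camera p = 1.68e-08), and without the mRNAs with upstream reading frames it did too (5.24e-07), which argues against either part as the whole source. With an estimated correlation the unadjusted p was 0.0253 and 0.0383, against 0.0193 for the whole list, whose adjusted p over the 29 lists was 0.193, so the shortened lists fare no better than the whole. Transcription of ATF4 targets, their loading onto ribosomes and the coding length of the other members stay open.

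Among the 153 genes raised 2-fold or more, some are known from other tissues and had low control signal, such as Amy1, for which no raised neighbour was found. The test of overlap ran on all 153, not on the dim genes alone. A share of 11.8% had another raised gene within 1 kb, against 7.32% of genes matched on signal (one-sided permutation p = 0.0316). The interval for matched genes was 3.27% to 11.8%, with the observed share at its upper end, so overlap may account for some. The genes with a raised neighbour numbered 18, among them Kcnrg and Trim13, which count as each other's neighbour. Raised probe sets without a single gene name and genes farther away were not searched, so 18 is no upper limit. The list of nuclear or untranslated RNAs had a median of -0.047 with members on both sides of 0, so nuclear RNA in the fractions cannot be told apart from other sources by it. No biological explanation was tested for this pattern.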

How the results depend on the processing

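The list medians relative to genes of like signal, the shortened ATF4 lists and the 2-fold count by signal were chosen after seeing the data. The number of genes changed was 3546 to 3892 when each sample was left out, and the number of lists shifted 7 to 11. An adjusted p under 0.01 gave 2736 genes, 1488 higher and 1248 lower, and 5 lists, by its own construction. Testing every probe set gave 471 with a 2-fold change, 383 higher and 88 lower, because more features were tested. Lists shifted numbered 8 in the report, 5 among genes at or above the median of the table, 5 with the rank-based camera, 0 with an estimated correlation and 13 with fry; the cause was not tested. Gas5 turned to -0.72 with the mean of its probe sets, since its probe sets disagree. With the replicate block 4071 genes changed, 2097 higher and 1974 lower, 3902 of them among the 4573, and 7 lists shifted; the eIF4E-sensitive list then had an adjusted p of 0.0539, and no other tested list or named gene changed its call under the block. Same-numbered samples deviated together with correlations of 0.0609, 0.107 and -0.0214, and not every sample correlated best with its own number, so the numbers were not taken to pair samples. At an adjusted p under 0.05 the share of higher calls ran from 45.5% among genes at or above the median of the table to 53.5% without 4EGI-1 replicate 2. Quantile normalization and centring outside ribosomal proteins gave medians over all genes of -0.0239 and -0.0248. Of 2-fold changes, 123 higher and 26 lower genes lay at or above the median of the table. Signal over background was not used here, so dim genes are the least certain.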

Other observations

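All tests of gene families here were chosen after the result was seen; the splits of the samples were planned.

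Among 108 families of at least 20 genes that share a symbol stem, zinc finger genes of the Zfp stem stood out: 131 of 347 rose and 12 fell (median 0.15, camera adjusted p = 5.54e-11, adjusted p = 0.468 with an estimated correlation). Nucleoporin genes, which encode the nuclear pore, rose in 11 of 20 and fell in 1 (median 0.30, camera adjusted p = 7.23e-06, adjusted p = 0.468 with an estimated correlation). Small GTPase genes of the Rab stem fell in 18 of 70 and rose in 3 (median -0.12, adjusted p = 0.00696; adjusted p = 0.468 with an estimated correlation), and ubiquitin-conjugating and related genes of the Ube stem fell in 13 of 39 and rose in 1 (median -0.11, adjusted p = 0.0324; adjusted p = 0.718 with an estimated correlation). Small nucleolar RNA genes of the Snord stem fell in 11 of 31 and rose in 1 (median -0.20, adjusted p = 0.0341; adjusted p = 0.499 with an estimated correlation).

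Named after their values were seen, the long-protein genes that rose included Nup205, a nucleoporin gene (1.11 ± 0.07, SE), Cad, an enzyme of pyrimidine synthesis (1.10 ± 0.08), the chromatin remodeller genes Chd4 (0.81 ± 0.06) and Smarca4 (0.99 ± 0.07), and Brca1 (0.94 ± 0.06). The short-protein genes that fell included Nop10 (-0.72 ± 0.06), the RNA polymerase subunit gene Polr2l (-0.86 ± 0.09), the prefoldin gene Pfdn4 (-0.66 ± 0.07) and the spliceosome genes Snrpe (-0.67 ± 0.08) and Snrpd2 (-0.51 ± 0.06). The difference between the long-protein and short-protein medians of single arrays, relative to the controls, was 0.91, 0.76 and 0.85 with 4EGI-1 and between -0.03 and 0.04 in the controls. Short-protein genes with long transcripts fell too, among them Rab8b (-0.52 ± 0.06), Ywhag (-0.57 ± 0.07) and Nras (-0.28 ± 0.07), 12 of 21 in all. That list was written after the fall of the Rab family was seen. Of 207 probe sets that a ribosomal protein gene shares with other genes, 37 were lower, 3 higher and the rest did not pass. Their median was -0.16, and they were not tested as a group.

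The 6 samples can be split into groups of 3 in 10 ways. The real split gave 4573 changed genes and the highest of the others 0, and 1 split, the real one, gave as many. With 10 splits the share cannot fall under 0.05. Every other split mixes control and treated arrays in both groups, so the treatment difference adds to the spread within groups. The 0 calls there are therefore no measure of how many genes would be called without a treatment effect.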
